A study of Mus musculus with 2 samples.

How the data were processed

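RNA from prostate tumour tissue of 2 mice, both aged 16 months, was measured by RNA sequencing, with 1 library from each of 2 genotypes named Bcat_Only and Met_Bcat. Per the labels' protocols, total RNA was extracted from homogenised tissue, 200 ng per sample entered a stranded mRNA library kit with 10 cycles of PCR, and single-end reads of 51 bases were sequenced on an Illumina instrument. The tissue was taken whole and no sort of cell types is described, so each library holds RNA of tumour epithelium together with stroma, immune cells and whatever neighbouring tissue was dissected with it.

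The deposited table holds whole-number read counts per gene, not normalised, for 27376 genes with Ensembl identifiers, symbols, mm9 coordinates and strand, per the file headers. The exon length that the authors deposited for each gene, in bases, is per the file headers the total length of its exons, and it was used only to match random gene lists on length. The submitters' processing notes name TopHat2 version 2, HTSeq, edgeR and the mouse build mm9. The settings of alignment and counting, including the strand setting, are not given in the sources used here. Reads of genes that overlap on opposite strands can therefore not be assigned with certainty, and the same holds for near-identical genes, among them immunoglobulin segments, haemoglobin genes, angiogenins and the Svs3 pair. Each library's column was matched to its sample through the sample number in its heading, which the labels give as the sample's description. Per the file headers, the heading of the Bcat_Only column also names a beta-catenin exon allele and a PB Cre driver. All coordinates below are those of the table, on mm9. The reference annotation used for older gene symbols and for the copies of Rps2 is of another build, so none of its coordinates are given.

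Library sizes were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 0.955 for Bcat_Only and 1.05 for Met_Bcat. Counts were expressed as CPM, the usual count per scaled library size. For each gene the ratio of Met_Bcat to Bcat_Only was given with its 95% exact (Clopper-Pearson) interval, conditional on the gene's summed reads. A gene was counted as higher or lower when the end of this interval nearest to no difference was at least 2-fold, among genes with a mean of at least 1 CPM. Reads that passed through PCR without molecular identifiers are not independent molecules, so every interval and floor covers counting error only. With 1 library per genotype there was no replicate check and no test between genotypes: all differences compare these 2 libraries, not the conditions, and no p-value was computed for any gene. The exact test given later, of the proportions among 6 seminal vesicle genes, covers counting error between the libraries only. For a count of 0 the floor was 3 reads, worth 0.163 CPM in Bcat_Only and 0.142 CPM in Met_Bcat, and a fold against it is written as a lower bound. Such a bound uses this floor and not the interval used for ranking, whose end lies lower.

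Before the data were examined, 41 gene lists with 616 members were fixed from textbook markers and pathways, together with the scaling, the size rule, the alternatives and the rule for naming genes. Of these members 611 were found in the table, 3 of them through the reference's names, and 3 were unmatched. Members named under an older and a newer symbol were counted once. For each list the median over its measured members of the log2 ratio of CPM plus 0.5 was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was described as standing apart below the 2nd or above the 98th percentile, and lists with fewer than 5 measured members were given as values. The pseudocount understates the differences of weakly expressed genes. If list members varied independently, 1.6 of 40 lists would stand apart by chance. Members of a marker list tend to vary together, so with 1 library per genotype the number expected without a genotype effect is unknown. The genes named are Met, Ctnnb1, Hgf and Axin2, the 12 genes highest and the 12 lowest in Met_Bcat by the interval end nearest to no difference (leaving out predicted and clone-named features), and up to 4 members of each list by the same measure. Any other member of a list is given as a value. Some genes that this rule names are not reported here one by one, though they count in the lists they belong to.

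The procedure was tested on simulated data in which counts for the 14354 genes considered were drawn from the means and sizes of these 2 libraries and 200 genes were changed. The intervals held the true ratio for 95.4% of genes, and 0 unchanged genes passed the size rule. Of genes changed 8-fold, 99% were recovered, and of those changed 2.8-fold, 88%. Among 200 simulated lists of 15 genes with no added shift, 3.5% stood apart, and of 20 lists shifted 2-fold, 100% did. Both libraries were drawn as Poisson counts from the same means, apart from the changed genes. The simulation held no variation between animals, no difference in tissue composition and no correlation between genes. These rates therefore cover counting error alone.

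The alternatives were DESeq2 size factors (version 1.42.0), total counts alone, total counts without the 50 most abundant genes, other minimum CPM values, a 99% interval or none, a pseudocount of 2 CPM, 5 bins, the mean of a list in place of its median, and each list without its farthest member. Scaling to the median ratio of the luminal epithelial markers was added after the data were seen. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 was used for the remaining steps.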

Results

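Gene expression was measured in prostate tumours of 2 mice of the same age, 16 months, with the genotype names Bcat_Only and Met_Bcat. The labels do not describe the MET allele, so whether the HGF receptor MET was activated is not known from them. The Bcat_Only tumour came from the genotype with altered beta-catenin alone and the Met_Bcat tumour from the genotype that combines it with MET, as far as the genotype names state. The Bcat_Only library held 19301062 reads assigned to genes and the Met_Bcat library 20117724. At least 1 read was found for 18931 genes in Bcat_Only and for 18472 genes in Met_Bcat. With 1 library per genotype, every difference below compares these libraries, has no replicate check, and carries an interval for counting error only.

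The genes named by the genotypes were examined first. Met, the receptor of hepatocyte growth factor (ENSMUSG00000009376, mm9 chromosome 6, 17413800 to 17523980), had 3118 reads or 169 CPM in Bcat_Only and 3500 reads or 166 CPM in Met_Bcat, a log2 ratio of −0.027 (95% interval −0.097 to 0.043). Ctnnb1, which encodes beta-catenin (ENSMUSG00000006932, chromosome 9, 120838334 to 120869625), had 981 and 974 CPM, a log2 ratio of −0.011 (−0.040 to 0.018). The sign of both ratios turned when library sizes were taken as total counts, where they were 0.11 for Met and 0.12 for Ctnnb1. These values check the labels only in part. Per the file headers, the Bcat_Only column is named for a beta-catenin exon allele and a PB Cre driver, and the Met_Bcat column names no allele. A transgene of another species, or an allele lacking part of a gene, need not alter the total counted at the mouse gene. Hgf, the ligand of MET (ENSMUSG00000028864, chromosome 5, 16059368 to 16125257), was 5.80-fold lower in Met_Bcat (4.87 to 6.96), at 41.3 CPM in Bcat_Only and 7.12 CPM in Met_Bcat. Fibroblasts also express Hgf, and the fibroblast and collagen matrix list was 8.07-fold lower by its median in the same libraries. Axin2, a feedback target of beta-catenin signalling (ENSMUSG00000000142, chromosome 11, 108781663 to 108812097), had 342 and 452 CPM, a log2 ratio of 0.40 (0.35 to 0.45) that was below the 2-fold rule and turned to −0.031 under scaling to the luminal epithelial markers, an alternative chosen after the data were seen.

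Across the transcriptome the Met_Bcat tumour library had far less RNA of fibroblast, smooth muscle, neutrophil, macrophage, B and plasma cell, inflammatory cytokine and seminal vesicle genes than the Bcat_Only library, and higher medians of the basal, squamous, luminal, Wnt target, unfolded protein response and ribosomal gene lists. Of 14354 genes with a mean of at least 1 CPM, 635 (4.42%) were at least 2-fold higher in Met_Bcat and 2102 (14.6%) at least 2-fold lower by the near end of their interval. At 4-fold these counts were 251 and 1086, and at 16-fold 44 and 355. The median log2 ratio was 0.034, with quartiles of −0.55 and 0.34, and the correlation of log2 CPM between the libraries across genes, which are not independent replicates, was 0.83. Of the genes past the size rule, 76.8% were lower in Met_Bcat. Scaling to the luminal epithelial markers gave 376 higher and 2855 lower genes, of which 88.4% were lower.

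**Figure D1:**
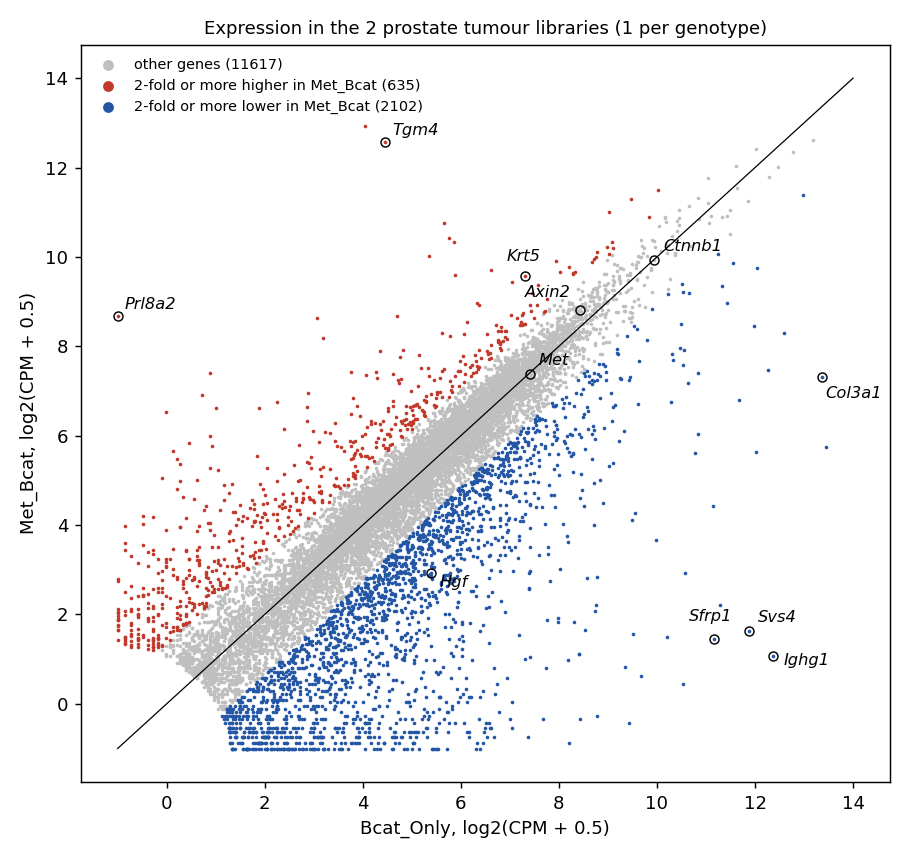
Expression of each of 14354 genes as log2 of CPM plus 0.5 in the Bcat_Only library (x axis) and the Met_Bcat library (y axis), with the line of equal expression, genes past the 2-fold size rule coloured and 11 genes named in the report circled. The 2102 lower genes (blue) outnumber the 635 higher genes (red), and Met, Ctnnb1 and Axin2 lie near the line.

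The 12 highest genes were of several kinds. Prl8a2, a member of the prolactin family (ENSMUSG00000018259, chromosome 13, 27437552 to 27446085), had 0 reads in Bcat_Only and 8590 in Met_Bcat, at least 2503-fold higher. Tgm4, the prostate transglutaminase (ENSMUSG00000025787, chromosome 9, 122943857 to 122976679), stood at 21.5 CPM in Bcat_Only and 6044 CPM in Met_Bcat, 281-fold higher (255 to 311). The endogenous retroviral gene Erv3 was 104-fold higher (68.1 to 169), the apolipoprotein gene Apoc1 50.2-fold (42.6 to 59.5) and the transporter-like gene Svopl 65.6-fold (40.2 to 115). Pnlip, pancreatic lipase, was 67.4-fold higher (38.4 to 131), and Atp6v1c2, a subunit of the proton-pumping ATPase, 75.7-fold (38.2 to 176). The angiogenin genes Ang5 and Ang4 were 64.8-fold (44.7 to 97.7) and 57.9-fold higher (33.7 to 109). The remaining genes of this group each had 1 read in Bcat_Only: Fam115e, with 323 reads in Met_Bcat and a ratio of 282-fold (50.3 to 11186), Itln1, the lectin intelectin, with 243 reads and 212-fold (37.8 to 8424), and Kiss1, the kisspeptin precursor, with 219 reads and 191-fold (34.0 to 7596).

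The 12 lowest genes included immunoglobulin, seminal vesicle and matrix genes. Ighg1, an immunoglobulin heavy chain constant gene (ENSMUSG00000076614, chromosome 12, 114567187 to 114568734), had 96733 reads in Bcat_Only and 34 in Met_Bcat, 3255-fold lower (2329 to 4700), and Ighg2c was 601-fold lower (487 to 751). Over 232 immunoglobulin heavy and light chain genes, the share of all reads was 2.27% in Bcat_Only (exact interval 2.26% to 2.27%) and 0.00997% in Met_Bcat (0.00953% to 0.0104%). The seminal vesicle secretory genes Svs4, Svs5 and Svs2, neighbours on chromosome 2, were 1436-fold (1103 to 1906), 1735-fold (1097 to 2928) and 786-fold lower (519 to 1255). Svs6, from the same cluster, had 1527 reads in Bcat_Only and 0 in Met_Bcat, at least 582-fold lower. Pate4, a secretory gene also named Svs7 (ENSMUSG00000032099, chromosome 9, 35414678 to 35419520), was 2924-fold lower (1253 to 9007). Sfrp1, a secreted antagonist of Wnt ligands, had 42486 reads in Bcat_Only and 47 in Met_Bcat, 1034-fold lower (777 to 1408). Cilp, a matrix protein of cartilage, had 5417 reads against 1, a ratio of 6197-fold (1112 to 244806), and the microfibril gene Mfap4 had 3046 against 2, a ratio of 1742-fold (482 to 14393). Dmbt1, a mucosal scavenger receptor, was 1322-fold lower (641 to 3289), and Cxcl13, a chemokine for B cells, 1209-fold lower (555 to 3296).

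**Figure D2:**
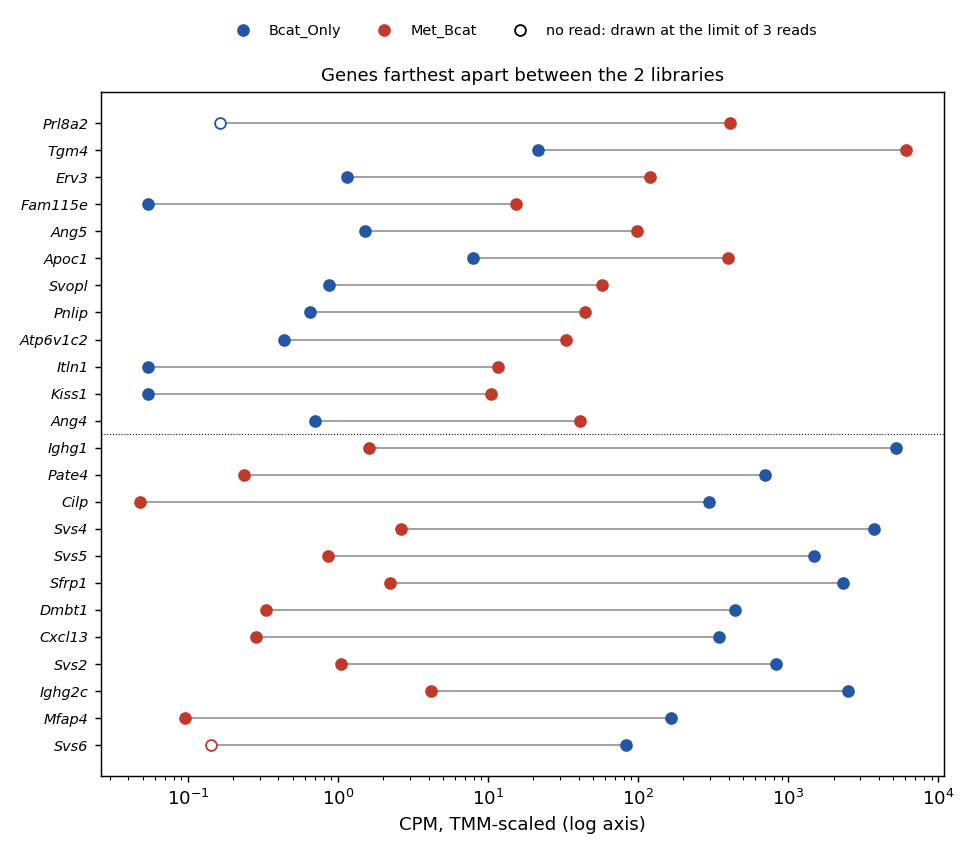
CPM, on a log axis, of the 12 genes highest (above the dotted line) and the 12 lowest in Met_Bcat, with a point for each library and a line joining the points of a gene; an open circle marks 0 reads, drawn at the floor of 3 reads. The floor stands for Prl8a2 in Bcat_Only and for Svs6 in Met_Bcat.

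Of 40 gene lists with at least 5 measured members, 11 stood apart as higher in Met_Bcat and 17 as lower. The sign of a small difference depends on the scaling. Relative to TMM, total counts raise every log2 ratio by 0.13, and scaling to the luminal markers moves it by −0.43. Under that last scaling, which sets the luminal median to 0 by construction, 5 of the 41 list medians changed sign, those of the oxidative phosphorylation, cholesterol synthesis, p53, stem and urothelial lists, and under the 3 other scalings 0 did. With the mean of a list in place of its median, the epithelial-mesenchymal transition, proliferation, hypoxia, interferon, MHC class II, Hedgehog, mucin and TGF-beta and BMP lists no longer stood apart.

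**Figure D3:**
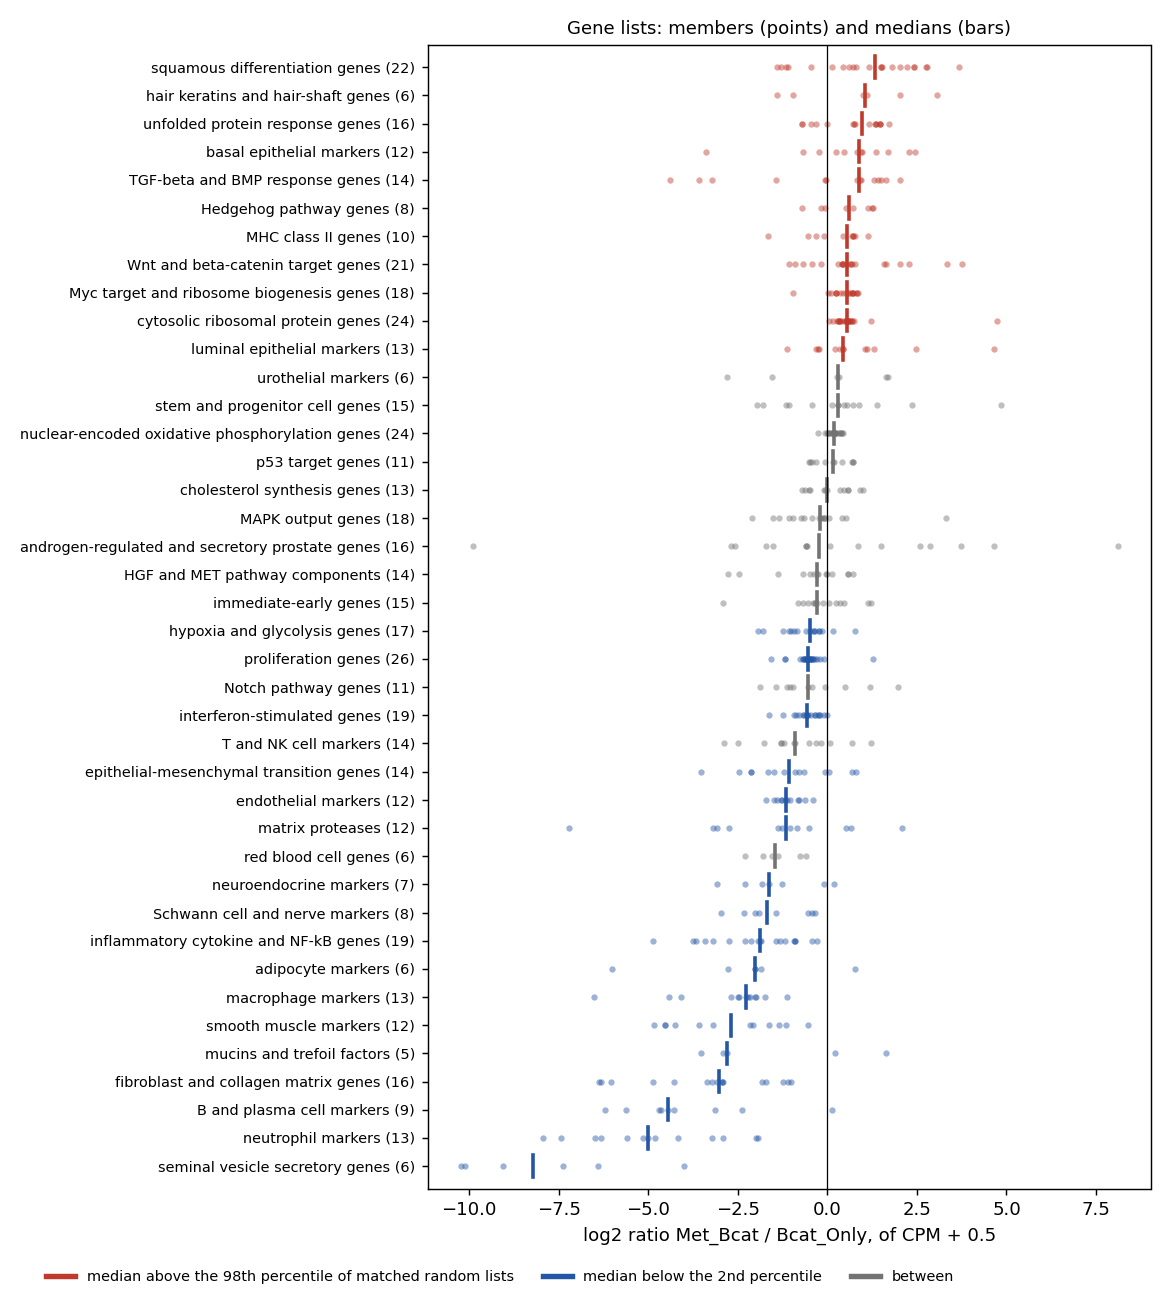
Log2 ratio of Met_Bcat to Bcat_Only, of CPM plus 0.5, for each measured member (points) and the median (bars) of the 40 gene lists, coloured by the median's percentile among matched random lists. The medians run from −8.22 for seminal vesicle secretory genes to 1.33 for squamous differentiation genes.

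The median of 21 Wnt and beta-catenin target genes was 0.56 (99.99th percentile), with 6 members higher and 1 lower by the size rule. Of the ratios 16 were above 0 under TMM, and 13 under scaling to the luminal markers, where the median was 0.13. Lef1, a transcription factor that binds beta-catenin, was 5.14-fold higher (4.21 to 6.34) and Bambi 4.17-fold (3.75 to 4.65). The Wnt inhibitor Dkk1 had 3 reads in Bcat_Only and 177 in Met_Bcat, 51.6-fold higher (17.4 to 252), and the growth factor gene Fgf20 had 1 and 108, a ratio of 94.4-fold (16.6 to 3763). The Wnt inhibitor Wif1 was 3.0-fold higher, while Cd44 was 2.11-fold lower.

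The 14 measured HGF and MET pathway components did not stand apart, with a median of −0.27 (2.72nd percentile), 0 higher and 3 lower members. Beside Hgf, the lower members were Hgfac, a protease that activates HGF, at 8.79-fold (6.07 to 13.1), and Plau, the urokinase gene, at 2.63-fold (2.30 to 3.0). St14, the matriptase gene, was 1.64-fold higher (1.58 to 1.70). The 18 MAPK output genes had a median of −0.20 (8.96th percentile). Of these, Areg, which encodes the EGF receptor ligand amphiregulin, was 14.2-fold higher (9.02 to 23.5), and 3 genes were lower, Plaur 4.42-fold, Emp1 2.86-fold and Dusp4 2.59-fold. The median of 15 immediate-early genes was −0.28 (4.85th percentile), with Egr1 2.19-fold higher (2.07 to 2.32) and Dusp1 7.80-fold lower (6.82 to 8.94).

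The luminal, basal and squamous lists had medians above 0 that stood apart. Luminal epithelial markers had a median of 0.43 over 13 members (99.1st percentile), 5 of them higher and 1 lower by the size rule, and no longer stood apart without the farthest member (0.39, 97.8th percentile). Hoxb13, a homeobox gene of prostate epithelium, was 5.69-fold higher (5.18 to 6.27), Foxa1 2.47-fold (2.35 to 2.60) and Krt19 2.15-fold (2.10 to 2.20), and Cldn7 was 2.20-fold lower. Androgen-regulated and secretory prostate genes went both ways, with a median of −0.24 over 16 members (8.78th percentile), 6 higher and 5 lower. The sign turned with the mean (0.27), with a minimum of 10 CPM (0.15) and without the farthest member, Pate4 (0.079). The list stood apart under none of these. Tgm4 was among the higher, and Pate4 and Spink3, with 50 reads against 0 (at least 19.1-fold), among the lower. Pate4, also named Svs7, had 12780 and 5 reads, and the seminal vesicle genes were lower in the same libraries (median −8.22). The list's share of all reads was 0.155% in Bcat_Only and 0.833% in Met_Bcat, where Tgm4 held 127387 of its 167543 reads. Fkbp5, an androgen-induced gene, was 2.85-fold lower.

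Basal epithelial markers stood above all matched random lists, with a median of 0.88 over 12 members, 4 higher and 1 lower. The basal keratin genes Krt5 and Krt14 were 4.85-fold (4.67 to 5.05) and 5.46-fold higher (5.11 to 5.84), and Trp63, the p63 gene, 3.24-fold (2.95 to 3.56). Krt15 was 10.9-fold lower (9.48 to 12.5). Squamous differentiation genes had a median of 1.33 over 22 members (100th percentile), with 11 higher and 1 lower. The median was 0.89 with a pseudocount of 2 CPM and 0.76 over 10 members with a minimum of 10 CPM, both apart, and it was the highest of the lists under neither. Krt16 was 21.2-fold higher (12.2 to 40.2), the desmogleins Dsg3 and Dsg1a 7.11-fold (5.99 to 8.49) and 12.1-fold (5.33 to 33.9), and the transglutaminase Tgm3 7.04-fold (6.19 to 8.03), while Tgm1 was 2.76-fold lower. Hair keratins and hair-shaft genes had a median of 1.05 over 6 members (99.99th percentile). The other 12 members found lay below the minimum expression, and the list's share of all reads was 0.0247% in each library. Krt33a, with 4 and 116 reads, was 25.4-fold higher (9.64 to 94.6) and Padi3 4.14-fold (3.64 to 4.73), whereas Tchh, trichohyalin, was 2.68-fold lower (2.52 to 2.85).

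Stem and progenitor cell genes went both ways, with a median of 0.30 over 15 members (95.6th percentile), 3 higher and 4 lower. Lgr6 was 38.6-fold higher (26.2 to 59.3) and Sox2 5.66-fold (4.44 to 7.30), and Aldh1a1 and Prom1 were 3.91-fold (3.78 to 4.05) and 3.48-fold lower (3.21 to 3.78). The 6 urothelial markers had a median of 0.30 (89.6th percentile), which turned to −1.04 over 9 members with a minimum of 0.2 CPM and to a mean of −0.066, neither apart, with Upk1b 3.25-fold and Gata3 3.13-fold higher and Upk3a 14-fold and Upk1a 3.43-fold lower. Neuroendocrine markers were lower, with a median of −1.62 over 7 members (0.97th percentile; 2.84th without the farthest member, no longer apart), led by Ncam1 at 8.75-fold (7.68 to 10.0) and Syp at 7.84-fold (4.46 to 14.9). Chga and Chgb had 46 and 48 reads in Bcat_Only and 10 and 8 in Met_Bcat. The Schwann cell and nerve list was lower in the same libraries, with a median of −1.68, and whether nerve contributed these reads was not tested. Mucins and trefoil factors had a median of −2.8 over 5 members (0.30th percentile), which was −0.90 and no longer apart with a minimum of 0.2 CPM, with Muc1 15.6-fold (10.6 to 23.7), Muc4 10.2-fold (6.36 to 17.4) and Muc5b 8.21-fold lower (6.70 to 10.1) and Agr2 3.29-fold higher (2.71 to 4.02).

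Matrix and stromal genes were lower as groups. Fibroblast and collagen matrix genes had a median of −3.01 over 16 members, 15 of them lower by the size rule, a median difference of 8.07-fold. Col1a2 was 84.3-fold lower (79.3 to 89.7), Col3a1 65.8-fold (63.6 to 68.1), the cross-linking enzyme gene Lox 82.4-fold (72.9 to 93.5) and biglycan, Bgn, 29.4-fold (28.2 to 30.7). Over 43 collagen genes the share of all reads was 2.67% in Bcat_Only (2.66% to 2.68%) and 0.278% in Met_Bcat (0.276% to 0.281%). Smooth muscle markers had a median of −2.68 over 12 members, 11 of them lower, with Cnn1 57.0-fold (24.1 to 177), Actg2 32.5-fold (21.7 to 51.1), Tagln 31.0-fold (25.7 to 37.7) and Myh11 27.9-fold lower (20.8 to 38.2). Both lists lay below all matched random lists. Endothelial markers were lower by less, with a median of −1.15 over 12 members (0.04th percentile), 7 of them lower, among them Tek 3.42-fold (2.91 to 4.02) and Egfl7 2.92-fold (2.47 to 3.47). The 12 matrix protease genes and inhibitors had a median of −1.16 (0.05th percentile), 6 of them lower and 1 higher by the size rule, Mmp10 at 5.77-fold (3.59 to 9.75), with Mmp3 199-fold (140 to 293), Timp1 9.28-fold (8.66 to 9.95) and Mmp9 6.70-fold lower (6.35 to 7.08).

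Genes of epithelial-mesenchymal transition had a median of −1.06 over 14 members (0.16th percentile), 7 of them lower and 0 higher. The lower members were led by Sparc at 11.5-fold (11.3 to 11.8), Fn1 at 5.50-fold (5.39 to 5.62), Snai1 at 4.70-fold (3.79 to 5.87) and Vim at 4.40-fold (4.23 to 4.57), genes that fibroblasts also express, and the fibroblast list had a median of −3.01 in the same libraries. Adipocyte markers had a median of −2.03 over 6 members (0.23rd percentile), or −3.03 over plain ratios without the pseudocount and with the count of 0 at the floor, and Cfd, the adipsin gene, had 578 reads against 0 (at least 220-fold lower). Adipoq had 60 reads against 1, a ratio of 68.6-fold (11.9 to 2756). Schwann cell and nerve markers had a median of −1.68 over 8 members (0.31st percentile), or −2.08 over plain ratios with the count of 0 at the floor, and −0.77 with a minimum of 0.2 CPM, where the list no longer stood apart, with the myelin gene Cnp 4.12-fold lower (3.70 to 4.58). Of the skeletal muscle markers 2 were measured, Tnni2 with 40 and 18 reads and Mylpf with 26 and 38, at a median of −0.36. The 6 seminal vesicle secretory genes had a median of −8.22, below all matched random lists, or −9.40 over plain ratios without the pseudocount and with the 3 counts of 0 at the floor.

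Neutrophil, B and plasma cell and macrophage markers were lower, and T and NK cell markers did not stand apart. Neutrophil markers had a median of −5.01 over 13 members (−5.09 over plain ratios with the count of 0 at the floor), all 13 lower by the size rule. Mpo, the myeloperoxidase gene, had 1886 reads in Bcat_Only and 2 in Met_Bcat, a ratio of 1079-fold (298 to 8914), Ngp was 296-fold lower (226 to 397), Camp 246-fold (105 to 759), and Elane had 434 reads against 0 (at least 165-fold). B and plasma cell markers had a median of −4.44 over 9 members (−6.25 over plain ratios, −2.88 with a pseudocount of 2 CPM), 8 of them lower, with Pou2af1 122-fold (59.0 to 305) and Ms4a1 76.1-fold lower (29.4 to 281), and Cd79b at 240 reads against 1, a ratio of 275-fold (48.8 to 10889). The median of 13 macrophage markers was −2.26 (−2.28 over plain ratios with the count of 0 at the floor), all 13 lower, with Mrc1 22.1-fold (19.5 to 25) and Itgam 17.2-fold lower (15.6 to 19), and Cd163 at 828 reads against 0 (at least 316-fold). These 3 lists lay below all matched random lists. T and NK cell markers were at a median of −0.91 over 14 members (4.64th percentile), with Cd4 9.57-fold (6.54 to 14.5), Cd2 13.7-fold (6.01 to 38.6) and Gzma 3.95-fold lower (2.81 to 5.66). Red blood cell genes had a median of −1.46 over 6 members (2.79th percentile; 1.44th with a pseudocount of 2 CPM and 1.07th with a minimum of 0.2 CPM, both apart), and the haemoglobin gene Hbb-b1 was 2.65-fold lower (2.37 to 2.97).

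Inflammatory cytokine and NF-kB genes had a median of −1.89 over 19 members, below all matched random lists, with 14 members lower and 0 higher. The neutrophil chemokine gene Cxcl1 was 41.1-fold lower (27.5 to 64.6), Il6 46.3-fold (17.8 to 172), Ccl20 15.3-fold (11.4 to 21.1) and the acute-phase gene Saa3 10.7-fold (10.4 to 11.1). Interferon-stimulated genes had a median of −0.56 over 19 members (0.91st percentile), with all 19 ratios below 0 under TMM and 17 under total counts. Of them, 2 passed the size rule, Rsad2 at 3.28-fold (2.62 to 4.13) and Gbp2 at 2.39-fold lower (2.14 to 2.68). MHC class II genes went the other way, with a median of 0.56 over 10 members (99.7th percentile), none past the size rule as higher. Cd74, the invariant chain gene, was 1.63-fold higher (1.59 to 1.68) and H2-Eb1 1.72-fold (1.63 to 1.81), while H2-Ob was 4.16-fold lower (2.57 to 7.01). The mean of this list was 0.18 and did not stand apart.

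Proliferation genes had a median of −0.53 over 26 members (0.15th percentile), with 25 ratios below 0 (24 under total counts), 2 members lower and 1 higher by the size rule. The mean of the list, −0.52, lay at the 15.5th percentile and did not stand apart. Mki67, the Ki-67 gene, was 2.29-fold lower (2.16 to 2.42) and E2f1 3.27-fold (2.45 to 4.42), while the ribonucleotide reductase gene Rrm2 was 2.44-fold higher (2.23 to 2.68). Hypoxia and glycolysis genes had a median of −0.47 over 17 members (0.62nd percentile), with Car9, carbonic anhydrase 9, 8.01-fold (3.61 to 21.0), Egln3 3.47-fold (3.24 to 3.72) and hexokinase 2, Hk2, 2.36-fold lower (2.22 to 2.50).

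Lists of protein synthesis and folding genes had medians above 0, with few members past the size rule outside the unfolded protein response. Unfolded protein response genes had a median of 0.97 over 16 members (100th percentile), with 7 higher and 0 lower by the size rule and 5 ratios below 0. Hspa5, the gene of the chaperone BiP, was at 1033 and 2888 CPM, 2.8-fold higher (2.75 to 2.84), Sdf2l1 was 3.29-fold higher (3.06 to 3.55), Manf 2.77-fold (2.65 to 2.89) and Herpud1 2.76-fold (2.65 to 2.89). Cytosolic ribosomal protein genes had a median of 0.54 over 24 members (100th percentile), with all 24 ratios above 0 under TMM and 15 under scaling to the luminal markers (median 0.11), and 2 members past the size rule. Rps2 was 30.6-fold higher (23.6 to 40.3), at 59 and 2064 reads, apart from the others, which lay at or below a log2 ratio of 1.25, and Rpl10a was 2.38-fold higher (2.12 to 2.66). Myc target and ribosome biogenesis genes had a median of 0.55 over 18 members (100th percentile), with 17 ratios above 0 under TMM, 11 under scaling to the luminal markers (median 0.12), and 0 past the size rule. Srm, spermidine synthase, was 1.82-fold higher (1.66 to 1.99) and Odc1 1.97-fold lower (1.71 to 2.26). Nuclear-encoded oxidative phosphorylation genes did not stand apart, at 0.19 over 24 members (86.6th percentile), with Cox4i1 1.29-fold higher (1.25 to 1.34), a direction that turned under scaling to the luminal markers. Cholesterol synthesis genes were at 0.0053 over 13 members (40.7th percentile), with Mvk 2.04-fold higher (1.74 to 2.40), and p53 target genes at 0.15 over 11 members (72.3rd percentile), with Cdkn1a 1.63-fold higher (1.52 to 1.74).

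Signalling lists other than Wnt were mixed. TGF-beta and BMP response genes had a median of 0.88 over 14 members (100th percentile) but a mean of −0.15 (40.8th percentile), which did not stand apart, with 5 members higher and 4 lower by the size rule. The BMP-linked Bambi was 4.17-fold, Bmp4 3.26-fold, Bmp2 2.85-fold, Smad7 2.67-fold and Smad6 2.54-fold higher, and the matrix-linked Ltbp2 was 21.5-fold (19.6 to 23.7), Ctgf 9.41-fold (8.60 to 10.3) and Tgfbi 2.71-fold lower. Hedgehog pathway genes had a median of 0.61 over 8 members (99.6th percentile), with Gli1 2.75-fold higher (1.86 to 4.14). Notch pathway genes had a median of −0.55 over 11 members (2.52nd percentile), which stood apart with a minimum of 10 CPM (−0.95) and without the farthest member (−0.75), with Hes1 4.01-fold higher (3.67 to 4.37) and Notch3 3.81-fold lower (3.27 to 4.45).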

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

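Of 311 list values under the alternatives, 295 kept the call of the list, and 27 lists kept it under every alternative run. DESeq2 size factors and total counts could change few calls, because rescaling a library shifts a list and its random lists almost alike. Counts of genes moved by more than 1.5 times with a mean of at least 10 CPM, to 356 higher and 1226 lower among 10500 genes, by the smaller set of genes considered, and with scaling to the luminal markers, added after the data were seen, to 376 higher. A pseudocount of 2 CPM and a minimum of 0.2 CPM made red blood cell genes stand apart (−1.15 and −1.54), and the minimum of 0.2 CPM ended the call of Schwann cell markers (−0.77) and of mucins (−0.90). Notch pathway genes stood apart with a minimum of 10 CPM (−0.95) and without the farthest member (−0.75), a setting that ended the call of luminal (0.39) and neuroendocrine markers (−1.45). The mean in place of the median ended the call of epithelial-mesenchymal transition (−1.10), proliferation (−0.52), hypoxia (−0.63), interferon (−0.58), MHC class II (0.18), Hedgehog (0.49), mucin (−1.48) and TGF-beta and BMP response genes (0.88 to −0.15). Beyond the construction of each alternative the cause was not tested. Total counts moved Met to 0.11, Ctnnb1 to 0.12 and Axin2 to 0.53, and leaving out the 50 most abundant genes moved Ctnnb1 to 0.054 and Axin2 to 0.47. Scaling to the luminal markers moved Met to −0.46, Ctnnb1 to −0.44, Hgf to −2.97 and Axin2 to −0.031. No paired analysis was possible because each genotype has 1 library. The depth limits genes with few reads: against a count of 0, a gene with 3 reads or fewer in the other library gives no fold.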

Other observations

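The families and genes in this paragraph and the next were chosen after their values were seen. Family counts cover only genes that reached the minimum mean expression, which a gene can reach through 1 library alone. Of 26 prolactin family genes in the table, 2 reached the minimum expression, Prl8a2 and Prl8a9, the latter with 0 reads in Bcat_Only and 67 in Met_Bcat (at least 19.5-fold higher). Prlr, the prolactin receptor gene, was 6.43-fold higher (6.0 to 6.91). Among single genes, Tpbpa was higher, at 0 and 132 reads (at least 38.5-fold), as were Cyp11a1, which encodes a steroid-synthesis enzyme, at 30.7-fold (19.5 to 51.4) and the progesterone receptor gene Pgr at 23.8-fold (14.9 to 40.6). All 3 genes of the pancreatic lipase family were higher, with 1467 reads in Bcat_Only and 39310 in Met_Bcat, most of them from Pnliprp1, which was 34.3-fold higher (32.1 to 36.6). Of 5 angiogenin genes 4 were higher, or 5 under total counts, and of 4 beta-defensins 3 were, with Defb1 16.1-fold higher (14.6 to 17.7). Keratin genes were higher for 13 of 22 and lower for 1, or 10 and 3 under scaling to the luminal markers. Pou2f3, a transcription factor gene, was 28.1-fold higher (18.9 to 43.7).

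Hox genes went both ways: 3 of 26 were higher, Hoxa10, Hoxa13 and Hoxb13, and 8 were lower, the 5 genes Hoxb2, Hoxb4, Hoxb6, Hoxb7 and Hoxb8 and the 3 genes Hoxd3, Hoxd12 and Hoxd13, the last 7.09-fold (5.71 to 8.88). Scaling to the luminal markers left 1 higher and 11 lower, and total counts gave 5 higher and 8 lower. Of 25 genes in the table that match a symbol pattern for complement genes, 19 were considered. The pattern can also match genes of other function, which were not removed. Of the 19, 13 were lower, led in reads by C3 at 27.6-fold (26.7 to 28.5). Higher were 2, C4bp and C1rb, the latter at 22.3-fold (21.0 to 23.8). All 79 kappa light chain genes considered were lower, with 257966 reads in Bcat_Only and 1453 in Met_Bcat. The fibroblast growth factor genes Fgf10, with 336 reads and 2, a ratio of 192-fold (52.8 to 1593), Fgf7, 19.3-fold (12.1 to 32.4), and Fgf2, 28.4-fold (15.2 to 59.9), were lower, as was Sfrp4, with 336 reads and 0 (at least 128-fold). The fibroblast growth factor family was not tallied, and its member Fgf20 went the other way, at 1 and 108 reads. Of the 4 secreted frizzled-related protein genes with an Sfrp symbol 2 were lower, Sfrp1 and Sfrp4, and 1 was higher, Sfrp5 at 5.01-fold (3.80 to 6.71). Members of the family under other symbols were not tallied. Of 36 collagen genes 20 were lower and 5 higher, among them the basement membrane genes Col7a1 at 3.10-fold (2.64 to 3.66) and Col4a6 at 4.76-fold higher (4.10 to 5.55). The clone-named gene 9530053A07Rik, outside the rule for named genes, was 483-fold higher (431 to 543), at 16.1 and 7788 CPM.

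Of the tests below, the comparison of endothelial with neutrophil markers and the test of the seminal vesicle proportions were chosen only after the results were seen. The lower stromal, immune and inflammatory lists could reflect how much non-epithelial tissue each sample held. A lower share of all such tissue by the same factor would move the markers of every cell type alike. The lower quartile of the endothelial members, −1.33, lay above the upper quartile of the neutrophil members, −3.21, a gap of 1.89 on the log2 scale. Against the fibroblast members, with an upper quartile of −1.79, the gap was 0.46. The endothelial and neutrophil lists had the highest and the lowest median of the 7 lists compared below, so a gap between them was nearly fixed in advance. An equal dilution alone would not give such gaps, unless other cells also express the endothelial genes, which was not tested. Unequal shares of cell types, whether from the genotype, the individual mouse or the piece of tissue taken, stay open and were not tested. A loss of long transcripts in Met_Bcat is argued against by random lists matched on expression and exon length, among which 7 of 7 lists stayed below the 2nd percentile (highest percentile 0.01), and the rank correlation of log2 ratio with exon length across genes was −0.0087.

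The lower seminal vesicle genes may come from a single source of seminal vesicle RNA that held a lower share of the Met_Bcat sample, such as adjoining gland in the dissected tissue. The 6 genes had 113891 reads in Bcat_Only and 95 in Met_Bcat, and a single source would keep their proportions. An exact conditional test with 100000 draws found no difference in these proportions beyond counting error (p = 0.103). However, 95 reads leave room for moderate shifts, as Svs2 had 22 reads where 12.6 were expected. Its share of the 6 genes' reads was 13.3% in Bcat_Only and 23.2% in Met_Bcat. Svs6, Svs3a and Svs3b had 1.27, 0.64 and 0.12 expected reads in Met_Bcat, too few to show a difference. They still add to the spread of the draws, so the result may depend on including them. Svs2, Svs4 and Svs5 were not tested alone, and whether the proportions were kept is not settled. Any origin of the 95 reads that keeps these proportions would pass, so the test cannot tell where they came from. Pate4, also named Svs7, was not part of the test. How many of these genes the tumour epithelium itself transcribes was not determined, so a lower secretory output of the Met_Bcat tumour stays open.

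Rps2 stood apart from the 23 other listed ribosomal protein genes, with 59 reads in Bcat_Only where their median was 1564, and 2064 in Met_Bcat where it was 2336. A split of reads between Rps2 and annotated near-identical copies could lower its count. Summed over Rps2 and the 6 copies in the table with at least 90% identity, the reads were 116 and 2133, a log2 ratio of 4.01 against at most 1.25 for the others, which argues against a split among these genes. Reads lost to 43 copies in the reference that the table does not list, and a strain variant within Rps2 that hinders alignment, stay open. A loss to copies would act on both libraries alike, unless they differ in sequence or in expression of the copies. Which of these applies was not tested, and a biological difference in Rps2 alone was not tested either.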
